A study of Drosophila melanogaster with 6 samples.

How the data were processed

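RNA was profiled by polyA-selected RNA-seq in 6 Drosophila melanogaster libraries, 3 in which the driver Mex-Gal4 expressed an RNAi construct against the splicing factor gene 9G8 and 3 in which it expressed a control double-stranded RNA against GFP. Mex-Gal4 drives expression in enterocytes, the absorptive cells of the midgut. The groups were taken from the sample titles and genotypes, and the replicates carry the letters A, B and D in both groups. The labels disagree on the tissue of the controls, whose source is given as fat bodies, and the series design names a yolk driver where the titles name Mex-Gal4, so the levels of tissue marker genes are reported for each library and no sample was regrouped. Nothing in the labels says that the 3 samples of a group came from separate cohorts of flies, so the p-values measure the spread between these samples.

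The deposited values are whole-number read counts per gene, not normalized, with 1 file per library and 17411 genes in each. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b and featureCounts from Subread 1.5.2 were used with the genome build BDGP6. The order and settings of these tools, the strand setting, the treatment of reads that map to several places and the annotation release are not given in the sources used here. Each file also gives the deposited summed exon length of every gene, per the file headers. Reads in exons shared by overlapping genes, and reads that fit near-identical copies of a gene, may therefore be assigned differently from the transcripts they came from.

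Gene symbols were taken from Ensembl annotation release 115. Of the gene identifiers, 17137 were found there, 210 older ones were named by position with at least 80% reciprocal overlap, and 64 stayed unnamed. Start and end were the same for 98.4% of the matched genes, and coordinates are given as in the deposited files. The number of introns of a gene was taken as the largest number of non-overlapping exons in its counted model minus 1.

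Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, library sizes were scaled by TMM, and the groups were compared with the robust quasi-likelihood test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are CPM values (counts over library size) scaled by TMM unless total counts are named, and log2 fold changes are 9G8-RNAi minus control, with SE. In all, 38 gene lists were fixed beforehand and tested on log2 CPM with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with the correlation estimated from the data and with fry as alternatives. The fry test for mixed directions was picked out for the text after its values were seen. The set of genes without introns was tested in the same way. Tables were joined with Python 3.11.15. For the target gene an exact two-sided permutation test was added. The edgeR and camera tests, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the target gene, then up to 10 genes per direction with the largest fold changes among those past the threshold, with a mean of at least 5 CPM and no overlap between groups, and up to 4 members of each list described, chosen by adjusted p among members past the threshold and otherwise by mean CPM.

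The edgeR and camera steps were tested on simulated counts for the 9G8-RNAi comparison, drawn for 9285 genes from the means, dispersions and library sizes of these libraries. Of the genes changed 2-fold, 4-fold and 8-fold, 4.69%, 42.9% and 79.7% were recovered, and 7 of 8779 unchanged genes were called. A shifted list of 50 genes reached a camera adjusted p of 1.29e-12 and an unshifted one 0.56. Genes were drawn independently of each other in this simulation. It therefore cannot show how often camera calls unchanged lists whose genes are correlated. In the real libraries the estimated correlation was 0.62 for the cytoplasmic ribosomal protein list.

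Total counts ranged from 26216430 to 66562756 per library, so that 3 counts, taken as the floor for a gene at 0, correspond to 0.045 to 0.114 CPM. This floor covers counting error only. All pairs of libraries differed by far more than sampling noise, with a chi-square per degree of freedom of at least 245.6, so none was treated as a repeat of another. The lowest value was between groups, for 9G8-RNAi replicate B and control replicate D, against at least 294.9 within a group. Only counting noise enters this test, so it does not show that libraries came from separate flies. The alternatives were RLE and upper-quartile factors, total counts only, no low-count filter, a filter of over 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a 2-fold threshold, library sizes computed without the 20 genes with most counts, the replicate letters as a block, and leaving out each library. Added after seeing the data were a term for libraries with many low-count genes, removal of the trend with exonic length from each library, and both together. Splicing itself was not analysed here, since the files give 1 count per gene.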

Results

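The series compared intestines with RNAi against 9G8, an SR-type splicing factor encoded by the gene x16, with controls carrying a double-stranded RNA against GFP. There were 3 libraries per group. Total counts were 29419928, 43017221 and 66562756 in 9G8-RNAi replicates A, B and D and 26216430, 47502677 and 31908476 in control replicates A, B and D. After filtering, 9285 genes were tested.

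The target gene was measured first, as a check of the labels. The x16 transcript (FBgn0028554, chromosome arm 2L from 6914301 to 6920210, minus strand, BDGP6) stood at 8.16 ± 2.92 CPM (SD, n = 3) in 9G8-RNAi and 11.8 ± 7.13 CPM (SD, n = 3) in control libraries. The single values were 6.37, 11.5 and 6.59 CPM against 8.29, 7.15 and 20.03 CPM, so the groups overlapped. The log2 fold change was -0.53 ± 0.46 (SE), with an edgeR adjusted p of 0.92 and an exact two-sided permutation p of 0.5, where 3 against 3 libraries cannot go below 0.1. This corresponds to 0.69 times the control level with a 95% interval from 0.33 to 1.44, so a fall of x16 transcript was not detectable in these libraries. Without control replicate D the log2 fold change, scaled by TMM, was 0.18, against -0.53 with all libraries. TMM factors differed widely, from 0.635 in control replicate D to 1.68 in control replicate A. In CPM of total counts the x16 values were 5.44, 9.76 and 7.69 in 9G8-RNAi and 13.9, 7.92 and 12.7 in control replicates A, B and D. These groups also overlapped (exact two-sided permutation p of 0.2), and control replicate D was not the highest. Of the 10 tested SR proteins, a family of splicing factors with x16 among them, 0 passed over all genes and 0 adjusted over the list alone. SC35 measured 66.3 ± 26.1 CPM in 9G8-RNAi and 46.8 ± 26.3 CPM in control libraries (SD, n = 3), and B52 measured 40.3 ± 4.98 and 47.2 ± 7.25 CPM. Among 32 genes of the spliceosome, 0 passed over all genes and 0 adjusted over the list alone, and SmB stood at 81.9 ± 26.9 CPM against 51.3 ± 27.4 CPM. Without control replicate A camera called the spliceosome list lower (median -0.22, adjusted p 0.045, against 0.70 with all libraries).

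The question of which genes differ when 9G8 is targeted gave 8 genes that rose and 3 that fell in 9G8-RNAi libraries. All were expressed at low levels, with at most 6.55 CPM on average. The genes that rose include Cyp12d1-d, a cytochrome P450, Ect3, a member of the beta-galactosidase family, phr, a DNA photolyase, and p24-2, of the p24 family of cargo receptors of the early secretory pathway. Those that fell were Cyp6a17, another cytochrome P450, mthl8, a methuselah-like receptor, and CG4650. Cyp6a17 alone meets the rule for named genes, and the other 10 were chosen after their values were seen.

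CG34451 rose from 0.176 ± 0.045 to 7.143 ± 1.495 CPM (SD, n = 3), a log2 fold change of 5.30 ± 0.37 (SE) with an edgeR adjusted p of 0.0049. Ect3 rose from 0.202 ± 0.061 to 4.94 ± 0.81 CPM, by 4.63 ± 0.40 on the log2 scale, with an edgeR adjusted p of 0.010. For Cyp12d1-d the levels were 0.097 ± 0.040 CPM in control and 4.32 ± 1.13 CPM in 9G8-RNAi libraries, a log2 fold change of 5.45 ± 0.49. The p24-2 gene had 0 counts in the 3 control libraries together and 327 in the 9G8-RNAi libraries, which is at least 82.8-fold higher against a floor of 3 counts over the control group. Its exons overlap those of Unc-115b, so its counts are uncertain. CG30008 rose from 0.786 ± 0.263 to 6.30 ± 1.26 CPM and HP1D3csd from 0.832 ± 0.069 to 4.90 ± 1.20 CPM. CG13562 rose by 3.33 ± 0.40 (SE) on the log2 scale and phr by 3.07 ± 0.38, and their exons overlap those of Nap1 and Prosalpha1. Cyp6a17 (2R from 14873953 to 14875739) fell from 11.4 ± 3.53 to 1.73 ± 0.26 CPM, a log2 fold change of -2.71 ± 0.34 (SE) with an edgeR adjusted p of 0.038. mthl8 fell from 3.77 ± 0.93 to 0.088 ± 0.096 CPM and CG4650 from 5.82 ± 2.45 to 0.457 ± 0.057 CPM. Cyp12d1-d, Cyp6a17, p24-2 and HP1D3csd have close copies in the genome, Cyp12d1-p, Cyp6a23, eca and rhi, with which reads may be shared.

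**Figure D1:**
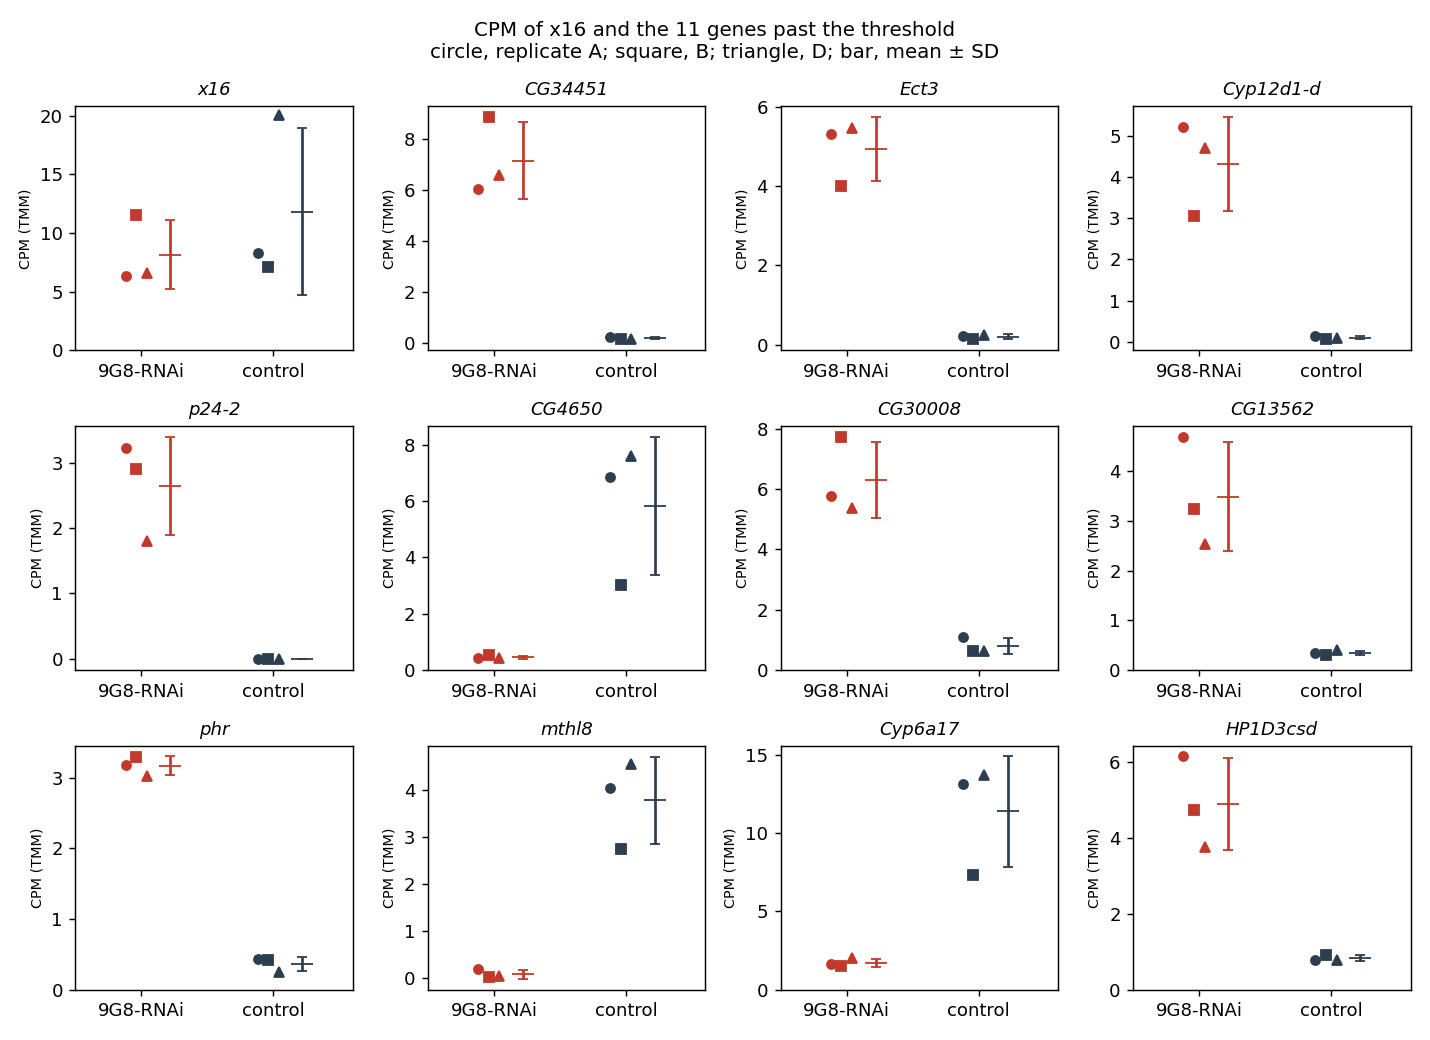
CPM values scaled by TMM of x16 and of the 11 genes past the threshold in each of the 6 libraries, one panel per gene, with red symbols for 9G8-RNAi, dark symbols for control and bars for the mean ± SD. The x16 values of the groups overlap, with 8.16 CPM on average against 11.8 CPM, while the values of each of the 11 genes do not.

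In this edgeR test, 421 genes had an unadjusted p under 0.05, against 464.25 expected by chance, and 8.61% of genes had no overlap between groups, where chance gives 10%. The number under 0.05 depended on the libraries: it ran from 253 without 9G8-RNAi replicate B to 633 without control replicate A and 1018 without control replicate D, and DESeq2 gave 568. Without 9G8-RNAi replicates A, B and D the number of genes past the threshold was 2, 0 and 2 (1 of the last shared), without control replicates A, B and D it was 11 (7 of them shared), 5 and 4, and with total counts only 9 were higher and 8 lower (52.9% higher, against 72.7% with TMM). Of these 17, 6 were among the 11, and CG30008, CG13562, phr, Cyp6a17 and HP1D3csd no longer passed. With limma-voom only 2 of the 11 passed, CG34451 and p24-2, and with the replicate letters as a block 0 passed.

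The libraries differed in ways that the groups do not explain. Control replicate A stood apart in muscle genes: Mhc, the muscle myosin heavy chain, measured 1418 CPM of total counts there and at most 40.3 CPM in the other 5 libraries. In the same library sls and bt, giant proteins of the sarcomere, measured 1217 and 986 CPM, against at most 16.5 and 16.4 CPM elsewhere. Genes outside the muscle list, picked out after their values were seen, also stood far higher there in CPM of total counts. CG6409 measured 2407 CPM against at most 61.7 CPM elsewhere, NKCC 607 against 10.8, Irk2 385 against 39.2 and Lgr1 161 against 4.03. The trypsin gene alphaTry was lowest in this library, at 25203 CPM. Genes with 0 counts numbered 5896, 5163 and 2079 in 9G8-RNAi replicates A, B and D and 3025, 2342 and 6091 in control replicates A, B and D. With a term for the 3 libraries with fewest genes at 0 (9G8-RNAi replicate D and control replicates A and B), chosen after seeing the data, 7 genes passed in the edgeR fit, and 6 of them, CG34451, Ect3, Cyp12d1-d, p24-2, CG4650 and mthl8, were among the 11. With the trend with exonic length removed as well, 3 passed, CG34451, Ect3 and Cyp12d1-d.

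The tissue of the controls was examined because the labels name both fat body and intestine. Digestive enzymes of the midgut were abundant in every library. alphaTry, a trypsin, took 25203, 49590 and 82379 CPM of total counts in control replicates A, B and D and 43329, 89330 and 84629 CPM in 9G8-RNAi replicates A, B and D. The protease Jon99Cii was present at 16241 CPM or more in all 6 libraries. The fat body list, 28 genes together, measured 828, 199 and 228 CPM in control replicates A, B and D and 902, 480 and 285 CPM in 9G8-RNAi replicates A, B and D. Lsp2, a storage protein of the fat body, was at 0.102 CPM or less in every library. The yolk protein genes Yp1, Yp2 and Yp3 lay between 17.7 and 220.3 CPM in all 6 and were highest in 9G8-RNAi replicate A. Other genes of the fat body list, picked out after their values were seen, were highest in control replicate A. There fon measured 70.6 CPM against at most 6.59 CPM elsewhere, apolpp 82.8 against 44.6 and Tep4 128 against 33.1. Genes of the ovary list summed to 8.09 CPM or less and those of the male tract to 2.06 CPM or less.

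**Figure D2:**
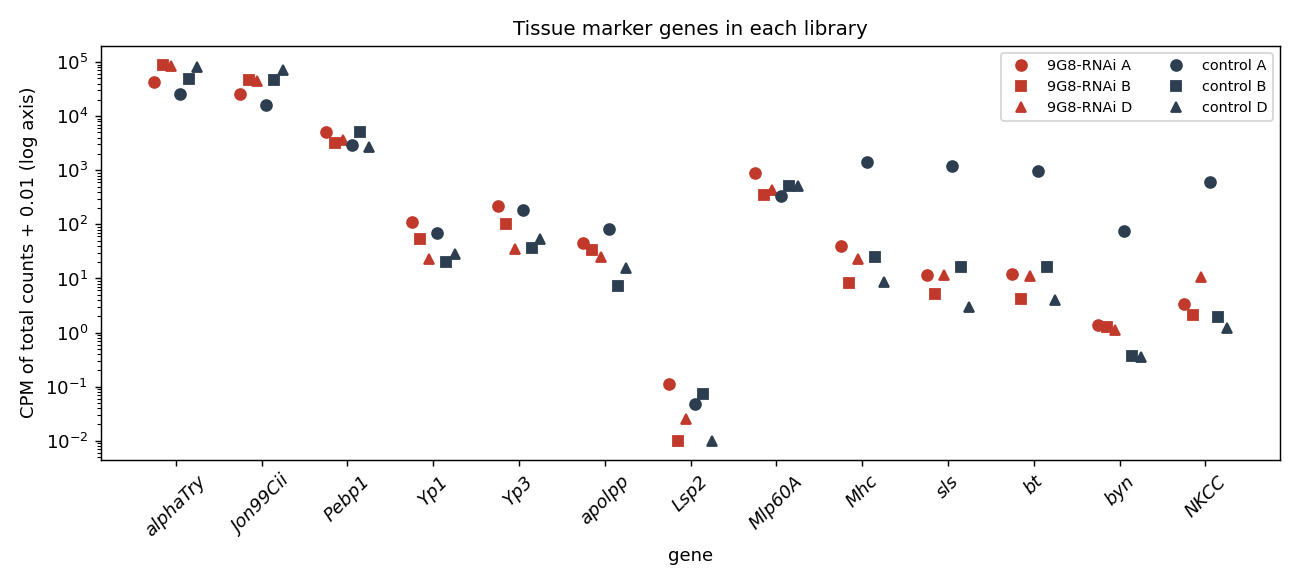
CPM values of total counts, plus 0.01, on a log axis for midgut genes (alphaTry, Jon99Cii, Pebp1), fat body genes (Yp1, Yp3, apolpp, Lsp2), muscle genes (Mlp60A, Mhc, sls, bt), byn and NKCC, with one symbol per library. alphaTry lies at 25203 CPM or more in all 6 libraries, and Mhc reaches 1418 CPM in control replicate A against at most 40.3 CPM elsewhere.

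Of the 35 lists with at least 3 tested members, camera with the preset correlation called 3 higher and 3 lower in 9G8-RNAi. Genes of cytoplasmic ribosomal proteins were higher as a list, with 79 of 85 members above 0, a median log2 fold change of 0.43 and a camera adjusted p of 8.7e-08. Those of mitochondrial ribosomal proteins followed, with 65 of 74 above 0, a median of 0.31 and an adjusted p of 1.4e-05, and the oxidative phosphorylation list had 52 of 67 above 0, a median of 0.25 and an adjusted p of 0.026. Lists that were lower were ER stress and ATF4 (22 of 24 members below 0, median -0.27, adjusted p 0.013), glycolysis and lactate (13 of 14, median -0.36, 0.034) and the cell cycle (23 of 27, median -0.41, 0.038). With an estimated correlation all 6 had an adjusted p of 0.91, and with fry the adjusted p was 0.87, so none of these calls held in either. No single member of the 6 lists passed over all genes, and 0 members passed adjusted over the list alone.

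RpLP2, of the ribosomal stalk, measured 7706 ± 4392 CPM in 9G8-RNAi and 4962 ± 2966 CPM in control libraries (SD, n = 3), and RpL41 measured 6670 ± 3598 and 4634 ± 2491 CPM. The mean log2 CPM of the cytoplasmic ribosomal list was 10.45, 10.28 and 9.59 in 9G8-RNAi replicates A, B and D and 9.13, 9.79 and 10.14 in control replicates A, B and D, so the groups overlapped. COX5A, a respiratory chain subunit, stood at 2121 ± 812 against 1694 ± 1121 CPM. Pdi, a protein disulfide isomerase of the endoplasmic reticulum, measured 233 ± 65.3 against 348 ± 121.6 CPM and the chaperone Hsc70-3 214 ± 114.5 against 314 ± 91.8 CPM. Eno, the glycolytic enolase, measured 202 ± 17.8 against 340 ± 169 CPM, and RnrS, a ribonucleotide reductase subunit, 17.0 ± 3.27 against 20.9 ± 4.23 CPM. Across the tested genes, which are not independent replicates, the log2 fold change was lower for genes of greater exonic length (Spearman's rho -0.48), and cytoplasmic ribosomal protein genes are short, with a median of 916 bases against 2057 for other genes.

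Without single libraries the median ran from 0.15 (without control replicate A) to 0.82 (without control replicate D) for cytoplasmic and from 0.056 to 0.70, without the same libraries, for mitochondrial ribosomal proteins. Without control replicate A the camera adjusted p was 0.40 for cytoplasmic and 0.62 for mitochondrial ribosomal proteins, 0.23 for oxidative phosphorylation (median -0.04) and 0.11 for the cell cycle, and without 9G8-RNAi replicate A it was 0.83 for oxidative phosphorylation (median -0.07). The camera adjusted p also rose above 0.05 for ER stress without 9G8-RNAi replicate B (median -0.17, adjusted p 0.078) or control replicate D (-0.30, 0.084). For glycolysis it did so without 9G8-RNAi replicate D (-0.33, 0.17), control replicate B (-0.39, 0.10) or control replicate D (-0.24, 0.60). For the cell cycle it did so without 9G8-RNAi replicate B (-0.36, 0.069), 9G8-RNAi replicate D (-0.58, 0.067) or control replicate B (-0.24, 0.52). With all libraries these medians were -0.27, -0.36 and -0.41. With the library term the calls of mitochondrial ribosomal proteins (median 0.15, adjusted p 0.074), oxidative phosphorylation (0.95) and the cell cycle (0.19) were lost, and with the trend with exonic length removed from each library those of mitochondrial ribosomal proteins (median 0.083, adjusted p 0.25) and oxidative phosphorylation (0.62). The call of glycolysis was also lost with the replicate letters as a block (median -0.34, camera adjusted p 0.059). That of the cell cycle was lost with total counts only (median -0.76, 0.053), where the median of all genes was -0.33.

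**Figure D3:**
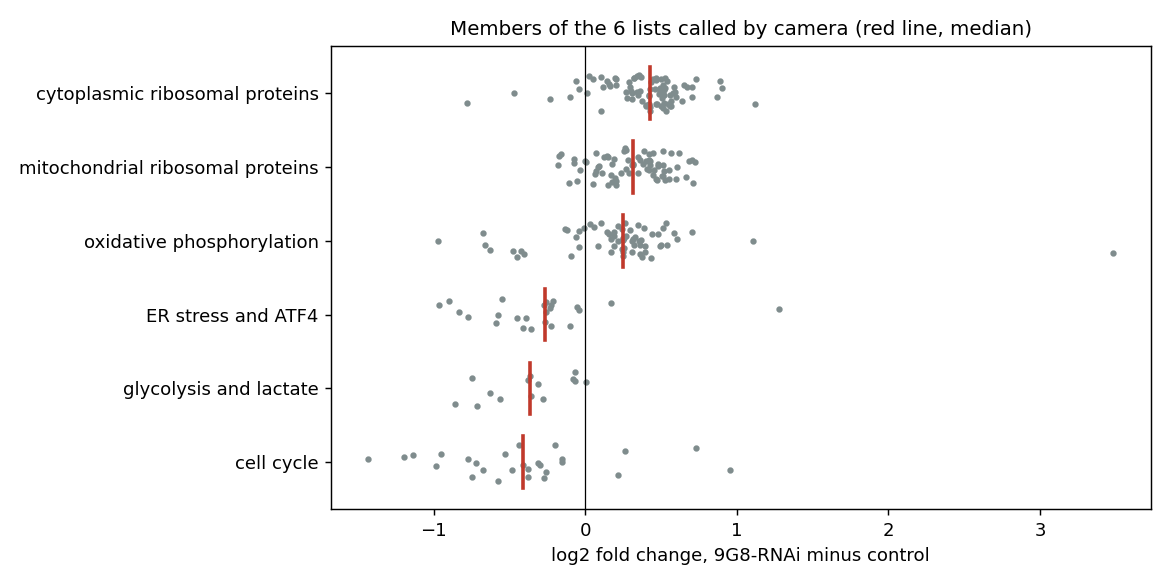
Log2 fold change, 9G8-RNAi minus control, of each tested member (grey points) of the 6 lists called by camera with the preset correlation, with the list median as a red line. The medians run from -0.41 for the cell cycle to 0.43 for cytoplasmic ribosomal proteins.

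The list of glutathione and xenobiotic response genes held both called P450 genes, with 1 member, Cyp12d1-d, that rose, 1, Cyp6a17, that fell and 31 that did not pass over all genes. Adjusted over the list alone, 4 were higher and 4 lower. Members thus moved in both directions, with a median of 0.13 and a camera adjusted p of 0.19, while the fry test for mixed directions gave an adjusted p of 0.0016. Cyp6a8, which in this edgeR fit passed only over the list alone, measured 19.1 ± 6.89 CPM in 9G8-RNAi and 1.32 ± 0.80 CPM in control libraries (SD, n = 3). Cyp6a9 measured 36.6 ± 1.37 against 12.2 ± 4.67 CPM. Cyp6a8 and Cyp6a17 lie close together on 2R, with 13244.5 bases between their midpoints. The changes in opposite directions may thus be partly local to this stretch, which was not tested. Lower values were seen for the glutathione S-transferase gene GstD8, with 1.47 ± 0.54 against 7.55 ± 3.55 CPM, and for Cyp28a5, with 7.39 ± 2.10 against 23.9 ± 6.57 CPM. In DESeq2, Cyp6a8 passed over all genes (adjusted p 4.75e-10), as did every other member named here or below as past the list threshold, save those of the tubule list. Cyp6a8 also passed over all genes in edgeR with no low-count filter (1.71e-04) and with the length trend removed (0.035). Outside the called genes, the members named in this and the following paragraphs as past the list threshold were chosen after their values were seen.

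Digestive and absorptive genes did not pass over all genes in any list. Among 12 trypsins 0 passed over all genes and 0 adjusted over the list alone, and alphaTry measured 76249 ± 27553 against 63162 ± 59523 CPM. Camera called the trypsins higher without control replicate D (median 0.61, adjusted p 0.0014) or 9G8-RNAi replicate D (0.43, 0.021) and with total counts only (0.15, 0.031), against 0.30 and 0.078 with all libraries. The 17 Jonah proteases gave 0 in both counts, and the direction of their list hung on single libraries, with a call lower without control replicate A (median -0.57, adjusted p 0.011) and higher without control replicate D (0.65, 0.0012). Of 18 carbohydrases, 0 passed over all genes and 2, Mal-A1 and Mal-A6, were lower adjusted over the list alone, with Mal-A1, a maltase, at 40.6 ± 8.40 against 109 ± 26.4 CPM. The carbohydrase list had a camera adjusted p of 0.14 and was called lower without 9G8-RNAi replicate A (median -0.61, 0.026) or control replicate B (-0.36, 0.013). Intestinal lipases had 0 of 15 over all genes and 4 adjusted over the list alone, CG31091 and CG31089 higher, CG17191 and CG6271 lower, and a fry adjusted p for mixed directions of 0.0016. In the list of lipoproteins and sterol transport 0 of 21 passed over all genes, and Npc2f and Npc2h were higher adjusted over the list alone. Npc2f, of a family of sterol-binding proteins, measured 165 ± 17.9 CPM in 9G8-RNAi and 51.1 ± 9.35 CPM in control libraries. For lipid synthesis and storage (27 tested), lipid breakdown (21) and sugar and amino acid transporters (16), both counts were 0.

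The antimicrobial peptide list had a median of -1.77 and a camera adjusted p of 0.14, or 0.91 with an estimated correlation. It was called lower without 9G8-RNAi replicate A (1.5e-04), 9G8-RNAi replicate B (4.9e-04) or control replicate B (5.5e-08), with total counts only (0.022), with the library term (2.3e-04) and with the length trend removed (0.017), while without control replicate D its median was -0.27 (0.60). Of its 8 tested genes 0 passed over all genes, and adjusted over the list alone Drsl2 was higher, at 6.90 ± 1.18 against 2.33 ± 1.06 CPM, and AttD lower, at 0.386 ± 0.158 against 2.93 ± 0.42 CPM, and the fry test for mixed directions gave an adjusted p of 0.0018. Both counts were 0 for the Imd pathway and PGRPs (16 tested), regeneration signals (14), cytoplasmic heat shock genes (11) and cell death genes (12). Hsp83, a chaperone, measured 122 ± 58.7 CPM in 9G8-RNAi and 286 ± 118.3 CPM in control libraries.

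Markers of gut cell types gave 0 in both counts for progenitors (15 tested), enteroendocrine cells (21) and enterocytes and midgut regions (18). esg, a transcription factor of progenitors, measured 10.03 ± 2.154 against 6.73 ± 0.90 CPM, Tk, an enteroendocrine peptide gene, 69.0 ± 34.0 against 63.9 ± 40.6 CPM, and Pebp1, of the enterocyte list, 4326 ± 1563 against 3486 ± 1551 CPM. Of other cell types, the visceral muscle list had 18 of 23 members below 0, a median of -0.75 and a camera adjusted p of 0.49, and its median was 0.45 (0.075) without control replicate A. Camera called it lower without 9G8-RNAi replicate A (median -1.12, adjusted p 0.033) or control replicate B (-0.81, 0.011). Malpighian tubule markers had 0 of 16 past the threshold over all genes, and NaPi-T, Oatp58Dc and salt were higher adjusted over the list alone. salt measured 133 ± 43.6 CPM in 9G8-RNAi and 44.0 ± 18.6 CPM in control libraries. The fat body list gave a median of 0.35 with a camera adjusted p of 0.16, hemocyte markers 0.47 with 0.28 and neuron markers -0.23 with 0.56, with 0 members past either threshold. These medians depended on single libraries: the fat body median was 1.15 (camera adjusted p 0.011) without control replicate A, 0.73 (2.7e-04) without 9G8-RNAi replicate D and -0.034 (0.82) without control replicate B, and with total counts only it was -0.19 while camera called the list higher (0.021). The hemocyte median was 0.70 (0.0095) without 9G8-RNAi replicate B and -0.21 (0.88) without 9G8-RNAi replicate A. For neuron markers it was 0.060 (0.71) without 9G8-RNAi replicate B, 0.037 (0.93) without control replicate B and -0.47 (0.062) without 9G8-RNAi replicate D. Insulin and nutrient signalling genes, peritrophic matrix genes and mucins, metal and acid handling genes, lysozymes and subunits of the vacuolar ATPase also had 0 members in both counts. Lists not called with all libraries were called lower without 9G8-RNAi replicate A for heat shock genes (camera adjusted p 0.0055), and without control replicate A for metal and acid handling (0.0023) and lysozymes (0.011). Called higher were tubule markers without 9G8-RNAi replicate A (0.0055) or control replicate A (0.021), lipoproteins and sterol transport without 9G8-RNAi replicate D (0.010), enterocyte markers without control replicate B (0.016) and xenobiotic response genes without control replicate D (0.043). With the length trend removed, lysozymes were called lower (0.031) and tubule markers (0.042) and lipid synthesis (0.031) higher, and with the library term lysozymes were lower (0.044). The sign of the list's test differed from that of its median for Jonah proteases, insulin signalling, enterocyte and Malpighian tubule markers, and median and mean differed in sign for intestinal lipases, tubule markers, peritrophic genes and the vacuolar ATPase.

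Genes were also grouped by introns, because 9G8 acts in splicing. The median log2 fold change was 0.07 for 1030 genes without introns and -0.08 for 8255 genes with introns, a difference of 0.15 with a camera adjusted p of 0.0086, or 0.16 with an estimated correlation (a single set, so adjusted and unadjusted p are the same). By intron number the median was 0.12 for 1 intron, 0.00 for 2 to 4, -0.20 for 5 to 9 and -0.36 for 10 or more, while the median exonic length rose from 1088 bases without introns to 6324 bases with 10 or more. The difference was 0.07 (camera adjusted p = 0.41) without 9G8-RNAi replicate B and 0.04 (camera adjusted p = 0.62) without control replicate A. With the trend with exonic length removed from each library, an alternative chosen after seeing the data, it was -0.03.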

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

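The library term and the removal of each library's trend with exonic length were chosen after seeing the data, and the other alternatives before. RLE and upper-quartile factors, and library sizes without the 20 top genes, gave 8 genes higher and 3 lower, as did a 2-fold threshold. DESeq2 called 62 higher and 42 lower, no low-count filter 34 and 16, the length correction 15 and 9, limma-voom 2 and 0, the library term 4 higher, and library term with length correction 3 and 0. Total counts only gave 8 lower and moved the median of all genes from -0.07 to -0.33. Leaving out single libraries gave 0 to 9 higher and 0 to 2 lower, with 253 to 1018 genes at an unadjusted p under 0.05. Of 198 fold changes of the 11 called genes under alternatives, 198 kept their direction and 85 no longer passed. The values of each of these genes did not overlap between groups, so the kept direction was nearly fixed beforehand. The cause of the shifts between alternatives was not tested.

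With the letters as a replicate block, edgeR gave 0 higher and 0 lower, with 217 genes at an unadjusted p under 0.05. The letters were not taken as pairs because nothing in the labels says that they mark a shared day or batch. Samples with the same letter did not deviate together (correlations of -0.02, -0.35 and -0.46 for A, B and D), and no sample correlated best with its own letter. The highest correlation between groups was 0.50, for 9G8-RNAi replicate B and control replicate D. Other structure among the libraries could thus hide a shared batch, so these correlations cannot decide on pairing. Without 9G8-RNAi replicate B, edgeR gave 0 genes, with 253 at an unadjusted p under 0.05, while DESeq2 called 104 and limma-voom 2 on all libraries.

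For x16 the log2 fold change ran from -0.86 to 0.18 without single libraries, turning direction only without control replicate D (0.18), and its adjusted p stayed between 0.85 and 1.00 in all alternatives. Lists called higher and lower numbered 0 and 0 with an estimated correlation and with fry. Total counts only gave 5 higher, the library term 1 higher and the length correction 5 lower. Without single libraries they numbered 2 to 6 higher and 1 to 7 lower, and oxidative phosphorylation ran from -0.071 (without 9G8-RNAi replicate A) to 0.72, turning also without control replicate A (-0.044). The intron difference ranged from 0.042 to 0.28 without single libraries, was 0.044 with the library term and turned to -0.035 with the length correction. Of 1918 group means of 137 list members, 251 moved by over 1 SD. Simulated 2-fold changes were recovered in 4.69% of cases, with the spread and depth of these libraries.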

Other observations

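The test of muscle genes as a single factor, the count of gene splits, the stricter count of neighbouring genes and the copy test for Cyp6a17 and p24-2 alone were chosen after the results were seen. The other tests were written before. For genetic background and for the length trend of ribosomal protein genes the reading was made more cautious than the bound first written, after the values were seen.

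Several genes just missed the edgeR threshold and had large differences. SMC2, a condensin subunit, measured 3.47 ± 2.53 CPM in 9G8-RNAi and 97.3 ± 50.6 CPM in control libraries (SD, n = 3), with an edgeR adjusted p of 0.059 and a DESeq2 adjusted p of 1.84e-12. SMC2 lies on 2R from 14848621 to 14852653, with 24209 bases between its midpoint and that of Cyp6a17. Unc-115b, which shares exons with p24-2, measured 0.936 ± 0.105 against 0.029 ± 0.026 CPM. These genes were chosen after their values were seen. Chemoreceptor genes, which are mostly used in sensory neurons, had counts for 29.6%, 40.3% and 93.0% of 186 genes in 9G8-RNAi replicates A, B and D and for 74.7%, 86.6% and 29.6% in control replicates A, B and D.

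The 11 called genes may reflect the RNAi, which was not tested separately, or differences in genetic background between the strains. Genes with an unadjusted p under 0.001 numbered 44 and formed 8 neighbouring pairs within 100 kb, against a median of 2 in 10000 random draws (permutation p = 0.0036), which met the bound written for background. Leaving out pairs that share exons or in which both genes carry only a number, which can be related copies, left 4 pairs (permutation p = 0.11), so background stays open. Reads moved from a close copy were tested by the summed CPM of gene and copy, which differed by 1.5-fold or more in 2 of 4 pairs. For Cyp12d1-d the sum differed 2.99-fold, against 43.7-fold for the gene alone. Cyp12d1-p itself did not fall, at 4.23 ± 0.66 CPM in 9G8-RNAi and 2.76 ± 1.26 CPM in control libraries (SD, n = 3). These values argue against moved reads as the whole difference, but moved reads may make up part of it. For HP1D3csd the sum differed 5.49-fold. Its copy rhi, at 0.044 CPM in 9G8-RNAi and 0.067 CPM in control libraries, held too few reads to be the source. For Cyp6a17 and p24-2 the sum differed by 1.5-fold in 0 of 2 pairs, and the larger copies could hide such a shift. Cyp6a23 measured 188 ± 25.3 against 202 ± 85.7 CPM and eca 38.1 ± 8.22 against 31.2 ± 11.4 CPM. The rule written beforehand also counted copies that moved the same way as their genes against moved reads. Cyp12d1-p, Cyp6a23 and eca did so, within their spread, and rhi did not. The real grouping gave 11 genes and the highest of the other splits 0, and 1 of the 10 splits reached the real value, too few splits for a share under 0.05.

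The muscle genes of control replicate A were 4.98-fold above the other controls at the median of 23 tested members. A length trend of that library was argued against: with the trend removed the median was still 2.01 on the log2 scale. More of the same gut muscle stays open as part of the pattern, since 56.5% of members lay within 3-fold of the median. Mlp60A was at 328 CPM of total counts there against 511 and 517 CPM in the other controls. Over the mean of the other controls, sls stood 125-fold, Mhc 83.8-fold, Mp20 1.55-fold and Mlp60A 0.64-fold. These members, picked out after their values were seen, thus did not rise by a common factor. Hindgut tissue may also have been present, since byn, a hindgut transcription factor, stood at 74.1 CPM against at most 1.39 CPM elsewhere, but of 6 further hindgut genes only 1, otp, was at least 4-fold above the other libraries with 0.1 CPM added to each value. FoxL1, at 0.877 against at most 0.165 CPM, passed 4-fold only without that addition, and either number is under the 3 genes asked for. Other genes far higher in that library, such as NKCC and CG6409, were not on this list, and their tissue was not examined.

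The higher level of ribosomal protein genes in 9G8-RNAi libraries may rest on single libraries: the camera call held in 5 of the 6 fits without 1 library and ended without control replicate A, and the group values overlapped. With the length trend of other genes removed, 49.3% of the list's median was left, just under the bound of 50% written for a length trend. The list still passed camera at the preset correlation after the trend was removed from each library (adjusted p = 0.017). With an estimated correlation the list was not called even before that removal (camera adjusted p 0.91), so this pass cannot argue against length. Length stays open as part of the pattern. An effect of the RNAi itself was not tested apart from these.

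For the lists, the real grouping gave 6 calls and the highest other split 14, and 9 of the 10 splits reached the real number, which points to structure among the libraries that does not follow the groups. For genes without and with introns the real difference was 0.15 and the highest other split 0.40, and 4 of the 10 splits were as large. In neither case can 10 splits give a share under 0.05.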
